A study of Caenorhabditis elegans with 24 samples.

How the data were processed

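Messenger RNA of 24 whole-worm samples was hybridised, 1 sample per array, to Affymetrix C. elegans Genome Arrays, from 5 µg of RNA each. The samples form 6 groups by RNAi plate (control, Rheb, TOR) and feeding (fed freely or fasted for 48 h), with 5, 4 and 3 arrays per feeding state, at day 4 of adulthood and 20 °C. The deposited values are GCRMA probe set intensities on a linear scale, and the version of GCRMA is not given in the sources used here. The authors name GeneSpring GX 7.3.1. GCRMA subtracts background and makes the distributions of the arrays alike, so that a change common to all transcripts cannot be seen.

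Intensities were turned into log2 values. Of 22625 probe sets, 77 are array controls, 20766 name 1 gene, 887 several and 895 none. Looking up symbols through Entrez numbers, for 20701 probe sets, changed none, and 65 could not be looked up. Each of 17118 genes was read by the probe set of highest mean, and the 12277 genes with a log2 value above 4 on at least 3 arrays were tested. Detection calls were not used. For named genes with a group mean below 4 the change was also computed with array values below 4 set to 4, which was decided after the data were seen and gives a lower bound for a comparison of 2 groups. Linear models with 6 group means were fitted to all 24 arrays in limma 3.58.1 under R 4.3.3 with moderated variances, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The 10 comparisons were fasted against fed on each plate, the 3 differences between these responses as interaction terms, and each knockdown against control in fed and in fasted worms. Targeted genes were also tested with exact permutation tests.

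Before the data were examined, 42 gene lists were fixed and tested with limma's camera at a preset correlation of 0.01, adjusted within each comparison, and beside it with an estimated correlation and with fry. Within a list, counts are of genes called over all genes, and "adjusted over the list alone" repeats the adjustment over its members. Named genes followed a fixed rule: the 2 targets and 9 anchor genes, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap (without that condition for interactions), and up to 4 members of each list with the smallest p. The share of the control response kept under a knockdown was the summed response over genes chosen at 2-fold on 3 control numbers, divided by that in the control arrays left out. In comparisons other than TOR RNAi in fed worms the added control RNAs bioB, bioC, bioD and cre were at -0.36 to 0.42.

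The labels call the samples biological replicates. Deviations from group means correlated between arrays of the same number for control and Rheb RNAi, and between fed and fasted TOR RNAi arrays, but not between TOR and the others, so a block by number is given as an alternative. The other alternatives were 3 variance models, 2 further scalings, 2 other filters, 2 treatments of probe sets, fits of the compared groups alone, and leaving out each array in turn. On simulated data with known changes, 98.2% of 4-fold and 30.4% of 1.5-fold changes were recovered for fasting in control worms, and 86.5% and 8.57% for the response under TOR RNAi against control. All columns of the deposited file were used. Probe sets naming several genes or none were left out of the gene counts, and where the sequences targeted by RNAi lie was not analysed here.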

Results

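Messenger RNA of whole wild-type (N2) Caenorhabditis elegans hermaphrodite cultures was measured on 24 Affymetrix C. elegans Genome Arrays, 1 per worm sample. The worms had been grown at 20 °C on plates carrying bacteria for RNA interference (RNAi), in which worms eat double-stranded RNA that lowers the matching transcript. The bacteria were a control, or targeted Rheb (rheb-1), a small GTPase that activates the TOR kinase, or TOR itself (let-363), the kinase that couples nutrients to growth. On each kind of plate worms either fed freely or were fasted for 48 h, and all were collected at day 4 of adulthood. This gave 6 groups: 5 arrays each of fed and fasted control worms, 4 each of fed and fasted Rheb RNAi worms, and 3 each of fed and fasted TOR RNAi worms. The series asks how fasting changes expression and how lowering Rheb or TOR changes that response. On every array 22625 probe sets were read, the median intensity lay between 46.9 and 58, and the number of arrays sets the precision of each value. Changes below are log2 differences between group means with their standard errors (SE), and rose, fell, higher and lower are used for limma's adjusted p under 0.05.
let-363 was lower on the TOR RNAi plates by both of its probe sets, and rheb-1 on the Rheb RNAi plates by 1 of its 2. let-363 fell by 1.45 ± 0.14 in fed and fell by 1.44 ± 0.14 in fasted TOR RNAi worms, with limma's adjusted p = 9.7e-08 and 1.2e-07. Its log2 intensity was 9.22 ± 0.23 (SD, n = 5) in fed control worms and 7.78 ± 0.08 (SD, n = 3) in fed TOR RNAi worms, and in fasted worms 9.26 ± 0.14 (SD, n = 5) and 7.82 ± 0.05 (SD, n = 3). A second let-363 probe set fell by 1.93 in fed and fell by 1.94 in fasted worms. Each of these 4 comparisons separated the arrays completely, and the two-sided exact permutation p was 0.0179, the smallest that 5 against 3 arrays allow. For rheb-1 the probe sets disagreed. The dimmer of its 2 probe sets fell by 2.55 ± 0.29 in fed and fell by 1.85 ± 0.29 in fasted Rheb RNAi worms in a fit of all probe sets, to 17.1% and 27.8% of control, with limma's adjusted p = 1.5e-06 and 8.6e-05 and two-sided exact permutation p = 0.00794 in both. Its intensity was 489 ± 147 (SD, n = 5) in fed control worms and 85.7 ± 31.4 (SD, n = 4) in fed Rheb RNAi worms. The brighter probe set, which stands for rheb-1 in the gene table, was at -0.3 ± 0.24 in fed and -0.5 ± 0.24 in fasted worms and passed in neither, with limma's adjusted p = 0.35 and 0.14. Its fed value depended on single arrays, at -0.18, -0.08, -0.47 and -0.49 without Rheb fed replicates 1, 2, 3 and 4, and was not called without any of them. Neither target was called in the other knockdown: rheb-1 was at 0.18 and 0.33 in fed and fasted TOR RNAi worms, and let-363 at 0.13 and 0.20 in fed and fasted Rheb RNAi worms. Fasting left both uncalled on every kind of plate. A probe set that reads sequence carried by the RNAi bacteria can pick up swallowed RNA, and where the targeted stretches lie is not given in the sources used here.

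**Figure D1:**
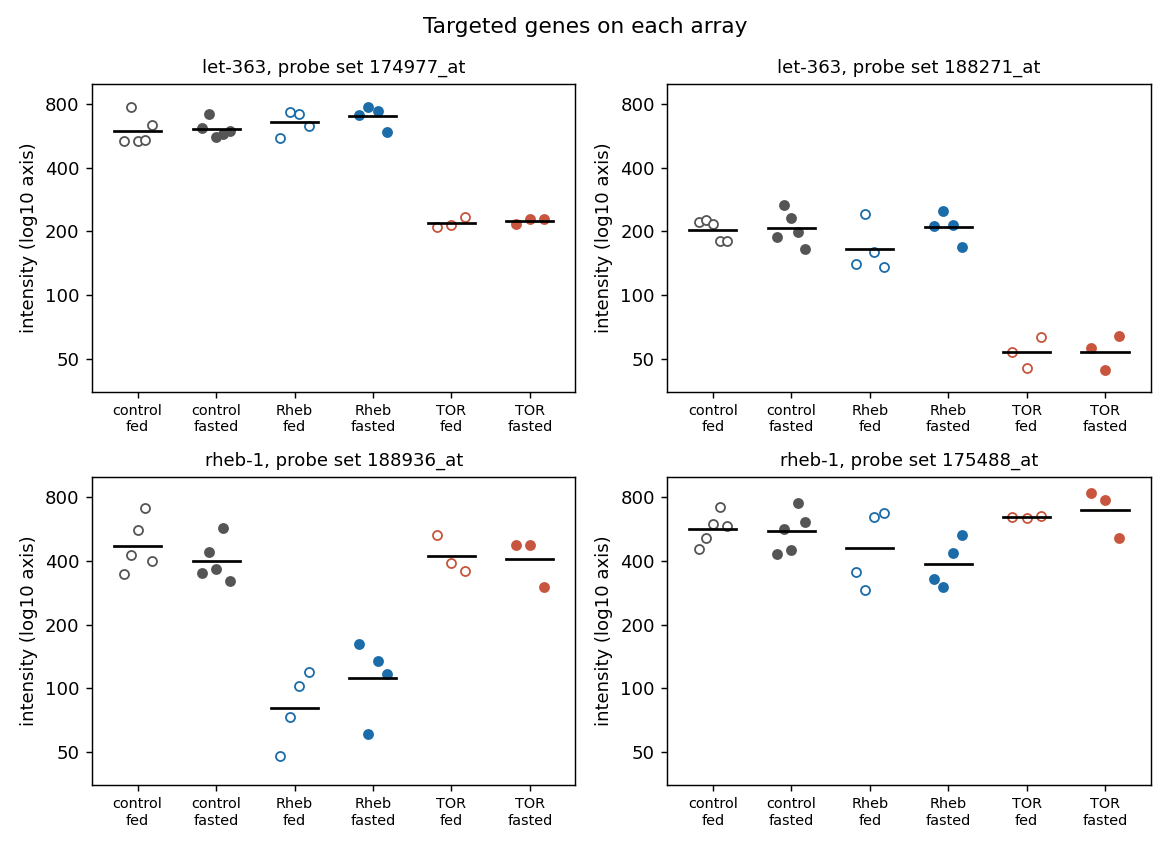
Intensity (log10 axis) of each let-363 and rheb-1 probe set on every array, with 1 point per array, 1 column per group and a bar at the group's geometric mean. Both let-363 probe sets were lower on all 6 TOR RNAi arrays, and the dimmer rheb-1 probe set (lower left) on all 8 Rheb RNAi arrays, than on any control array, while values of the brighter one overlapped.

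Single genes of fat use and stress protection were among the most changed transcripts of fasted control worms. acs-2, an acyl-CoA synthetase that feeds fatty acids into mitochondrial oxidation, rose by 6.78 ± 0.44 (adjusted p = 1.7e-10). The small heat shock protein genes hsp-12.6 and hsp-12.3 rose by 4.25 ± 0.3 and 4.36 ± 0.42, and the water and glycerol channel gene aqp-1 by 4.89 ± 0.48. ins-7, an insulin-like peptide gene, fell by 4.42 ± 0.27, and the fatty acid desaturase gene fat-7 fell by 1.74 ± 0.42. Of 12277 genes tested with limma, 2322 changed, 1351 higher and 971 lower in fasted worms, and 872 of them by at least 2-fold. The other large rises were of T22F3.11 (6.06), the alcohol dehydrogenase gene adh-1 (5.29), the lysozyme gene ilys-3 (4.90), clec-61 (4.66) and far-7 (4.48). The largest falls were of F55G11.2 (-6.47), sysm-1 (-6.05), ilys-5 (-5.53), C17H12.6 (-5.34) and C05D12.3 (-5.3). clec-61 in fed and C17H12.6 in fasted worms had means below log2 4, the limit of the filter, and with array values below 4 set to 4 the changes were at least 4.28 and 4.84. sod-3, which encodes a mitochondrial superoxide dismutase, rose by 0.62 ± 0.17 (adjusted p = 0.013). No call was made for daf-16 (-0.1), nhr-49 (0.18), vit-2 (-0.11) or gst-4 (-0.5).

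Groups of genes moved together in fasted control worms. Of 41 measured genes of the mitochondrial respiratory chain, 25 rose and none fell (32 rose adjusted over the list alone), by a median of 0.37. They included ucr-2.2 (0.62) of complex III, nuo-1 (0.49) of complex I and the ATP synthase gene atp-4 (0.56). Of 22 lysosomal and digestive peptidases, 15 fell and 1 rose (16 and 1 adjusted over the list alone), among them the cathepsin B-like cpr-1 (-2.95), cpr-4 (-3.26), cpr-5 (-3.78) and cpr-9 (-3.54). Of 11 genes known to be lower when the FOXO factor DAF-16 is active, 8 fell (9 adjusted over the list alone), with dod-24 at -2.7 and dod-22 at -3.13. These 3 lists passed limma's camera test with its preset correlation (adjusted p = 1.0e-10, 1.6e-10 and 3.3e-10), and they alone of 22 passing lists also passed with an estimated correlation (adjusted p = 0.031, 0.049 and 7.3e-04). Of 18 genes known to be higher when DAF-16 is active, 10 rose and 2 fell (11 and 2 adjusted over the list alone), hsp-12.6 and aqp-1 among the rises and the lysozyme gene lys-8 (-1.94) among the falls, with camera's adjusted p = 3.8e-04 and, with an estimated correlation, adjusted p = 0.37. Of 8 genes of the glyoxylate cycle, gluconeogenesis and trehalose, 5 rose and none fell (5 adjusted over the list alone), with the glyoxylate cycle gene icl-1 at 1.68, the trehalose synthase gene tps-1 at 1.29 and the phosphoenolpyruvate carboxykinase gene pck-2 at 1.08 (adjusted p = 0.33 with an estimated correlation). Of 105 cuticle collagen genes, 51 fell and 1 rose (57 and 2 adjusted over the list alone), led by col-183 (-3.45), col-101 (-2.98) and col-124 (-2.87), with adjusted p = 0.33 with an estimated correlation. Markers of cell types moved as well: 15 of 40 zygotic embryo markers rose and 1 fell (19 and 1 adjusted over the list alone; median 0.64), 9 of 45 neuron markers rose and 1 fell (10 and 1; median 0.39), and 3 of 12 intestine markers fell (4; median -0.3). Their adjusted p were 1.7e-04, 0.0016 and 0.025 with camera and 0.43, 0.49 and 0.39 with an estimated correlation. Germline and oocyte and eggshell markers lay the other way from the embryo markers, with medians of -0.22 and -0.23 and 8 of 36 and 4 of 27 genes above 0, and 8 of 34 hedgehog-related epidermal genes fell in both adjustments. These 3 lists had adjusted p = 0.0088, 0.021 and 0.0014 with camera and 0.54, 0.65 and 0.39 with an estimated correlation.

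Lists with members that went both ways included fatty acid beta-oxidation, in which acs-2 and hacd-1 (3.57) rose but acox-1.5 (-2.39) and acox-1.2 (-1.06) fell; 4 of 33 rose and 5 fell, as they did adjusted over the list alone, and the list did not pass (adjusted p = 0.81). Neither did fatty acid synthesis, desaturation and elongation (0.23), lipases and fatty acid binding proteins (0.52), heat shock proteins (0.067) or antioxidant enzymes (0.067). Of 28 lysozymes and saposins 12 fell and 4 rose (14 and 4 adjusted over the list alone), with lys-6 at -3.39 and spp-18 at -2.81 against the rise of ilys-3 (adjusted p = 0.39 with an estimated correlation). Ribosomal protein genes barely moved: 1 of 74, rps-13 (0.28), rose, none of them passed adjusted over the list alone, and the median was 0.08. The call of rps-13 was lost without any 1 of 5 arrays (control fed 1, 2 and 3, control fasted 2 and 4), at changes of 0.22 to 0.28, with arrays centred on their medians (0.26) and in a fit of the compared groups (0.28). With the replicate number as a block, which pairs the arrays, 3883 genes were called in place of 2322. The p-values measure the spread between samples called biological replicates, from experiments called independent.

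**Figure D2:**
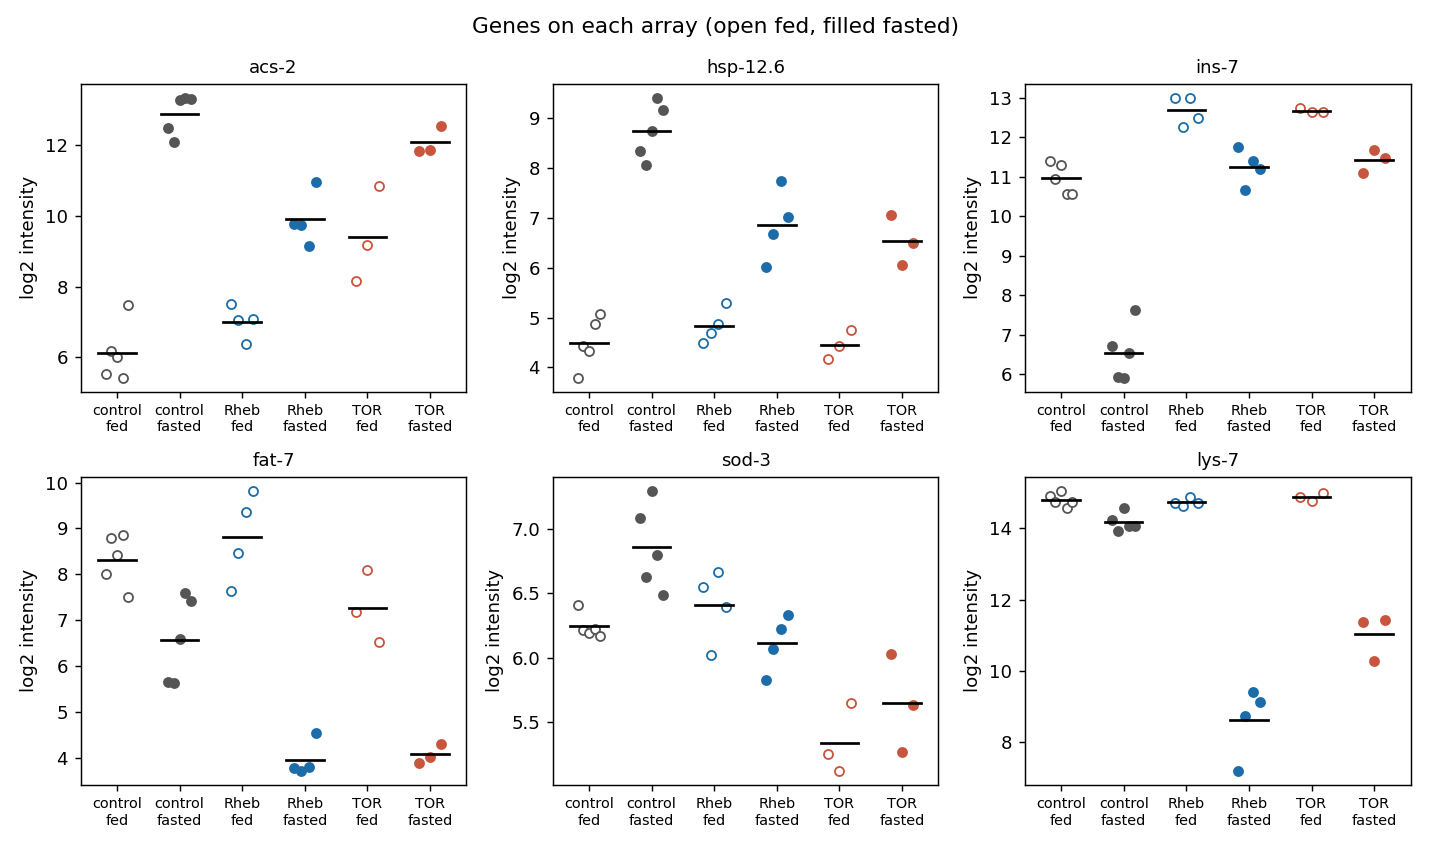
Log2 intensity of acs-2, hsp-12.6, ins-7, fat-7, sod-3 and lys-7 on each array, with 1 point per array, 1 column per group and a bar at the group mean. acs-2 rose with fasting by 6.78 in control worms, by 2.90 in Rheb RNAi worms and by 2.69 in TOR RNAi worms, and the fasted level of hsp-12.6 was lower under both knockdowns.

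Transcripts of digestive and lysosomal proteins were among the largest falls with fasting in Rheb RNAi worms. The peptidase genes cpr-1, asp-17 and cpr-9 were at -6.94 ± 0.27, -6.37 ± 0.3 and -5.89 ± 0.26, and the lysozyme genes lys-4 and lys-7 at -6.13 ± 0.28 and -6.13 ± 0.32. acs-2 and hsp-12.6 rose by 2.90 ± 0.49 and 2.02 ± 0.34, ins-7 fell by 1.43 ± 0.3 and fat-7 fell by 4.87 ± 0.47. Of the 12277 genes, 1461 changed, 397 higher and 1064 lower, and 798 by at least 2-fold. Other large falls were of spp-12 (-6.93), which encodes a saposin-like protein, T18H9.11 (-6.45) and C23H5.8 (-6.13). The largest rises were of T22F3.11 (4.06), adh-1 (3.23), aqp-1 (3.18) and F40G12.5 (3.0). Means below log2 4, the limit of the filter, leave lower bounds: the falls of asp-17, C23H5.8, fat-7, clec-41 and lipl-1 were at least 5.8, 5.87, 4.68, 4.42 and 2.27, and the rise of F40G12.5 at least 2.49. gst-4 fell by 1.86 ± 0.42, and sod-3 (-0.29), daf-16 (-0.1), nhr-49 (0.25) and vit-2 (-0.16) were not called.

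Of the 22 lysosomal and digestive peptidases 18 fell, also adjusted over the list alone, by a median of -2.6, and of the 28 lysozymes and saposins 19 fell and 2 rose (20 and 2 adjusted over the list alone). Of 99 C-type lectin genes 28 fell and 2 rose (30 and 2 adjusted over the list alone), with clec-41 at -4.64 and clec-62 at -3.74. Of genes of fat metabolism, 12 of 33 beta-oxidation genes fell and 1 rose (13 and 1 adjusted over the list alone), with acox-1.5 at -4.83 and the carnitine palmitoyltransferase gene cpt-5 at -3.42, and 10 of 17 genes of fatty acid synthesis, desaturation and elongation (11 adjusted over the list alone), with fat-5 at -2.32 and fat-3 at -1.74. The same held for 28 of 57 UDP-glucuronosyltransferases, against 2 that rose (31 and 2 adjusted over the list alone) with ugt-41 at -3.91, for 6 of 12 intestine markers (8 adjusted over the list alone) with ges-1 at -1.65 and the endoderm factor gene elt-2 at -0.84 (not called in a fit of the compared groups), and for 3 of 5 vitellogenins in both adjustments, with vit-1 at -3.48. The genes lower with active DAF-16 fell as well, 7 of 11 in both adjustments, with the acid ceramidase gene asah-1 at -4.37. All 9 lists passed camera and also passed with an estimated correlation, at adjusted p from 6.6e-04 (peptidases) to 0.043 (vitellogenins). Of the 19 lipases and fatty acid binding proteins 3 fell, lipl-1 (-3.17), lipl-5 (-2.56) and lbp-7 (-1.63), and 1, hosl-1 (0.45), rose (5 and 1 adjusted over the list alone; adjusted p = 0.0064 with camera and 0.31 with an estimated correlation). The call of hosl-1 was lost without any 1 of 19 of the 24 arrays (0.33 to 0.49), namely all but control fed 2 and 3, control fasted 1, Rheb fed 2 and Rheb fasted 4. It was lost too without Rheb fed 3 and TOR fasted 2, the arrays of highest 3' to middle ratio (0.49). So it was, at 0.45, in a fit of the compared groups, without a filter on dim probe sets, without the _s_at and _x_at types and with an intensity trend, robust or not. 13 of 26 muscle genes fell (17 adjusted over the list alone), with the troponin I gene tni-3 at -1.32 and the calponin-like gene unc-87 at -1.25, but with an estimated correlation the list had an adjusted p = 0.15. Of the other cell type lists that passed camera, germline and zygotic embryo markers had medians of 0.24 and 0.61, and 6 of 34 hedgehog-related epidermal genes fell (7 adjusted over the list alone), at adjusted p = 0.55, 0.31 and 0.28 with an estimated correlation. No respiratory chain gene was called among 41, in either adjustment, the list's median was 0.13, and its adjusted p was 0.046 with camera and 0.41 with an estimated correlation. A block by number called 2960 genes, 1502 higher and 1458 lower. Of 798 changed at least 2-fold without it, 61 rose and 737 fell. When each array was centred on its median, which moved the median change of all genes from 0.0891 to 0.155, the calls split into 760 higher and 1008 lower.
Fasting TOR RNAi worms lowered transcripts of digestive and lysosomal proteins too. ctsa-1.2, a cathepsin A-like carboxypeptidase gene, fell by 7.43 ± 0.35, cpr-1 fell by 6.56 ± 0.32, ilys-5 fell by 6.94 ± 0.42 and hrg-11.2 fell by 7.46 ± 0.5. acs-2 and hsp-12.6 rose by 2.69 ± 0.57 and 2.09 ± 0.39, ins-7 fell by 1.26 ± 0.35 and fat-7 fell by 3.20 ± 0.54. The call of ins-7 was lost without any 1 of the 3 TOR fed arrays or of TOR fasted replicates 1 and 3, at changes of -1.29 to -1.1. T22F3.11 rose the most, by 7.03 ± 0.82, followed by F10C2.7 (4.25) and C23G10.11 (4.07), and the chloride channel gene best-1 rose by 3.25. Of the 12277 genes, 766 changed, 133 higher and 633 lower, 593 of them by at least 2-fold. The other large falls were of sysm-1 (-7.91), F01D5.3 (-7.24) and K12H4.7 (-6.83). As means below log2 4 leave lower bounds, the falls of ctsa-1.2, F01D5.3 and lipl-1 were at least 7.3, 5.92 and 4.56 and the rise of F10C2.7 at least 3.54. sod-3 (0.31), gst-4 (-0.93), daf-16 (-0.35), nhr-49 (-0.01) and vit-2 (-0.38) were not called. gst-4 was called at an unchanged -0.93 with the replicate number as a block, and with the TOR numbers as blocks of their own so were gst-4 and vit-2 (-0.38).

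Of the 22 peptidases 18 fell (19 adjusted over the list alone) by a median of -2.78, with asp-17 at -6.02 and the cathepsin D-like asp-3 at -3.82. Of the lysozymes and saposins 17 of 28 fell and none rose (18 fell and 2 rose adjusted over the list alone), with lys-4 at -5.18 and lys-8 at -3.99. Of the C-type lectins 29 of 99 fell and 1 rose (33 and 2 adjusted over the list alone), with clec-50 at -4.51. The genes lower with active DAF-16 fell in 8 of 11 cases (10 adjusted over the list alone), with dod-24 at -5.79 and dod-19 at -4.29. Intestine markers fell in 5 of 12 cases (6 adjusted over the list alone), with the intestinal actin gene act-5 at -2.1 and the intermediate filament gene ifb-2 at -2.18, and vitellogenins in 3 of 5 (5 adjusted over the list alone), with vit-1 at -2.99. These 6 lists passed camera and passed with an estimated correlation too, the highest adjusted p being 0.042 (vitellogenins). Of the 19 lipases and fatty acid binding proteins 6 fell in both adjustments, lipl-1, a lysosomal lipase gene, by the most (-5.14), at adjusted p = 0.21 with an estimated correlation. Muscle genes and zygotic embryo markers, with medians of -0.49 and 0.53, passed camera and had adjusted p = 0.35 and 0.62 with an estimated correlation. No respiratory chain gene was called (median 0.20, adjusted p = 0.19 with an estimated correlation), and none passed adjusted over the list alone. Of the lists that passed both tests under Rheb RNAi, fatty acid synthesis, beta-oxidation and UDP-glucuronosyltransferases passed camera alone here, at adjusted p = 0.24, 0.19 and 0.17 with an estimated correlation. A block by replicate number gave 1298 called genes.
Whether fasting responses differed was tested as the log2 response under Rheb RNAi minus that under control RNAi. The acs-2 response was smaller by a difference of -3.88 ± 0.66 (adjusted p = 6.0e-04) and that of hsp-12.6 by -2.22 ± 0.46 (adjusted p = 0.0041), while the fall of ins-7 was smaller, with a difference of 2.98 ± 0.41 (adjusted p = 4.4e-05). ilys-3, raised by fasting in control worms, had the most negative difference, -6.22 ± 0.58, and the differences of the digestive genes cpr-2, lys-7, asp-17 and spp-12 were -6.14 ± 0.67, -5.51 ± 0.42, -5.18 ± 0.41 and -5.11 ± 0.57. Of the 12277 genes, limma called 600, 131 with a higher and 469 with a lower response under Rheb RNAi, 484 by at least 2-fold. C17H12.6, clec-67 and C05D12.3, lowered by fasting in control worms, had differences of 5.40 ± 0.41, 4.74 ± 0.34 and 4.52 ± 0.43. Of the 131, 114 (C17H12.6 and clec-67 too) were lower and 1 higher already in fed Rheb RNAi worms. fat-7 had a difference of -3.13 ± 0.63 and sod-3 one of -0.91 ± 0.25 (adjusted p = 0.037). The call of sod-3 was lost without any 1 of 12 of the 18 arrays compared, namely all but control fed 1, control fasted 2 and 5, Rheb fed 2 and Rheb fasted 3 and 4, at changes of -0.93 to -0.8. It was also lost without the 2 high-ratio arrays (-0.82), with arrays centred on their medians (-0.83) and with a further quantile normalization (-0.77). gst-4 (-1.35), daf-16 (-0.0), nhr-49 (0.07) and vit-2 (-0.05) were not called. Some group means of 4 genes were below log2 4, and with array values below 4 set to 4 the differences were -4.61 for asp-17, -2.95 for fat-7, 4.84 for C17H12.6 and 4.87 for C05D12.3. gst-4 was called at an unchanged -1.35 with the replicate number as a block, in which control and Rheb RNAi arrays pair.

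Of the 18 genes higher with active DAF-16, 10 had a lower and none a higher response (14 lower adjusted over the list alone), by a median difference of -1.76, with the cytochrome P450 gene cyp-34A9 at -5.31, dod-3 at -3.34 and lys-8 at -2.26. lys-8 fell in control worms and fell further under Rheb RNAi. lys-7 and lys-8 are also among the 28 lysozymes and saposins, of which 14 had a lower and 2 a higher response (16 and 3 adjusted over the list alone; adjusted p = 0.058 with an estimated correlation). Of the 22 peptidases 11 had a lower response (15 lower and 1 higher adjusted over the list alone). Of genes of fat metabolism, 11 of 17 genes of synthesis, desaturation and elongation (12 adjusted over the list alone), with fat-5 at -3.11, fat-6 at -1.73 and the elongase gene elo-6 at -3.16, and 8 of 33 beta-oxidation genes (10 adjusted over the list alone), with hacd-1 at -4.07 and the enoyl-CoA hydratase gene ech-7 at -3.66, had a lower response, and 1 beta-oxidation gene a higher one in both adjustments. These lists, the lysozymes apart, also passed with an estimated correlation (adjusted p = 0.021 for the genes higher with active DAF-16, the peptidases and both fat lists). Of the 8 glyoxylate, gluconeogenesis and trehalose genes 3 had a lower response (4 adjusted over the list alone), tps-1 (-1.3) and pck-2 (-1.14) among them, at adjusted p = 0.12 with an estimated correlation. The respiratory chain list shifted by a median of -0.23 with 2 members called in both adjustments, nduf-5 (-0.72) and asg-2 (-0.77), at adjusted p = 0.12 with an estimated correlation. asg-2 was not called without any 1 of 10 arrays (-0.78 to -0.67), namely control fed 2 and 3, control fasted 1, 3, 4 and 5, Rheb fed 3 and 4 and Rheb fasted 1 and 2. nduf-5 was not called without any 1 of 10 (-0.72 to -0.63), namely control fed 1, 2 and 3, control fasted 4 and 5, Rheb fed 1, 3 and 4 and Rheb fasted 1 and 2. Neither was called in a fit of the compared groups (-0.77 and -0.72) or without the 2 high-ratio arrays (-0.67 and -0.63). Lists of cell type markers passed camera too. The difference lay below 0 in muscle (median -0.58, with 0 of 26 genes above 0), neuron (-0.46, 5 of 45) and intestine markers (-0.43, 1 of 12), and above 0 in germline (0.40, 35 of 36), oocyte and eggshell (0.3, 23 of 27) and sperm markers (0.24, 37 of 44). Their adjusted p were 2.9e-04, 6.2e-04, 0.032, 1.0e-06, 0.015 and 0.018 with camera and 0.42, 0.52, 0.41, 0.25, 0.70 and 0.71 with an estimated correlation, and of their genes ges-1 (-1.43), csr-1 (1.23) and ssp-10 (-0.86) alone were called. The call of csr-1 was lost without any 1 of 12 of the 18 arrays compared, namely all but control fed 5, control fasted 2 and 3, Rheb fed 2 and Rheb fasted 3 and 4 (0.98 to 1.25), without a filter on dim probe sets (1.23) and without the 2 high-ratio arrays (0.98). That of ssp-10 was lost without Rheb fed 1 or Rheb fasted 3 (-0.76 or -0.72). camera passed 22 lists, 4 of which passed with an estimated correlation. A block by replicate number gave 1417 called genes.

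How much of the control response was kept was measured on genes chosen, at 2-fold, in 3 fed and 3 fasted control arrays and scored on the other control arrays, in all 10 choices of 3 numbers (478 to 714 genes). Under Rheb RNAi the summed response was 73.4% of that in the left-out control arrays (range over the choices 0.668 to 0.830 as a share). Genes that fasting raised kept a share of 0.286 (0.260 to 0.317), and genes that it lowered kept 0.930 (0.851 to 1.07). The median raised gene rose by 1.36 in the left-out control arrays and by 0.5 in Rheb RNAi worms. Against control worms in the same feeding state, it was at 0.89 (0.70 to 1.15 over the choices) in fed and at -0.01 (-0.38 to 0.28) in fasted Rheb RNAi worms, and the median lowered gene at -0.94 (-1.02 to -0.85) and -0.64 (-0.94 to -0.39). The shares are values without a test.

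**Figure D3:**
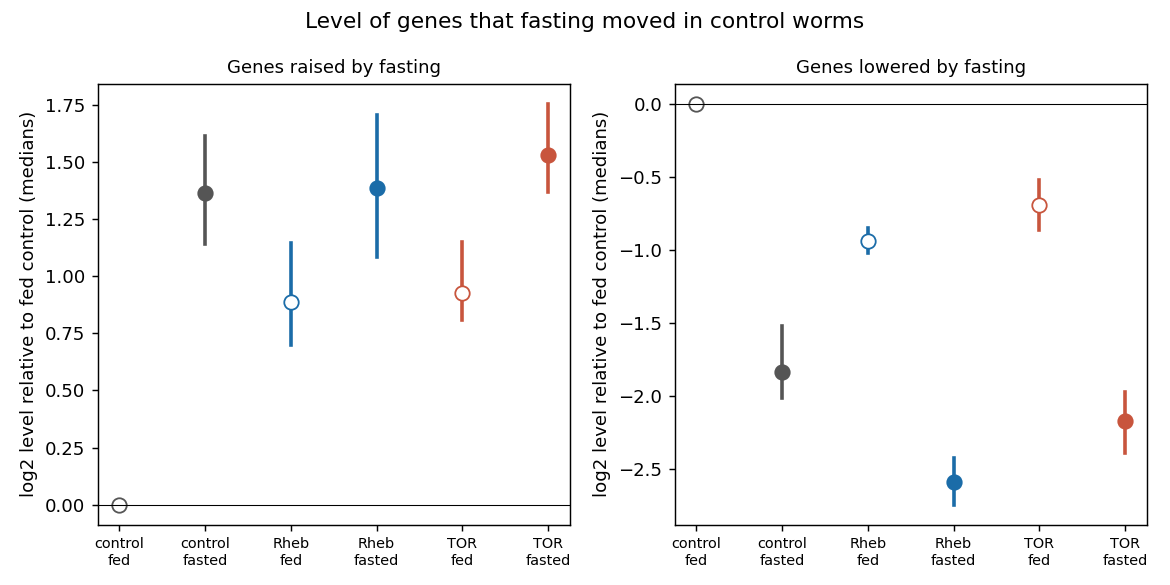
Median log2 level, relative to the left-out fed control arrays, of genes that fasting raised (left) or lowered (right) in control worms, in fed and fasted worms of each plate; points are means over the 10 choices of control arrays used to pick the genes, bars the lowest and highest choice, and fasted knockdown points add the median fasting response to the median fed level. Raised genes started 0.89 (Rheb RNAi) and 0.93 (TOR RNAi) above the fed control level.

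The fasting response under TOR RNAi also differed from that of control worms, and of the gene lists the peptidases and the genes higher with active DAF-16 passed both tests. The response of acs-2 was lower by a difference of -4.09 ± 0.72 (adjusted p = 0.0015), that of hsp-12.6 by -2.15 ± 0.5 (adjusted p = 0.018), and ins-7 fell less, with a difference of 3.16 ± 0.44 (adjusted p = 1.4e-04). Without TOR fed replicate 3 or TOR fasted replicate 2 the hsp-12.6 difference was -2.0 or -1.91 and not called, as it was, at -1.91, without the 2 high-ratio arrays. The most negative differences were those of cpr-2 (-6.99 ± 0.73), ilys-3 (-5.0 ± 0.63), asp-17 (-4.83 ± 0.44) and lys-10 (-4.68 ± 0.86), and the most positive those of F46F2.3 (4.44 ± 0.28), C17H12.6 (4.08 ± 0.45) and the cuticle collagen gene col-183 (3.68 ± 0.61). Of the 12277 genes, limma called 300, 86 with a higher and 214 with a lower response under TOR RNAi, 274 by at least 2-fold. Of the 86, 70 were lower and 3 higher in fed TOR RNAi worms. fat-7 (-1.46 ± 0.68, adjusted p = 0.41), sod-3 (-0.31), gst-4 (-0.42), daf-16 (-0.25), nhr-49 (-0.19) and vit-2 (-0.27) were not called. With array values below log2 4 set to 4, C17H12.6 and lipl-1, which had group means below it, were at 4.41 and -3.45.

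Of the 22 peptidases 11 had a lower response (13 lower and 2 higher adjusted over the list alone), with cpr-1 at -3.62 and asp-3 at -2.91, and of the 18 genes higher with active DAF-16 8 did (11 adjusted over the list alone), with lys-7 at -3.24 and dod-3 at -2.42. Both lists passed camera and passed with an estimated correlation (adjusted p = 0.024 for each). Of the 105 cuticle collagens 12 had a higher response and none a lower one (18 higher adjusted over the list alone), with col-101 at 2.28 and col-158 at 1.45, at adjusted p = 0.23 with an estimated correlation. Of the lipases and fatty acid binding proteins 5 of 19 had a lower response (6 lower and 1 higher adjusted over the list alone), with lipl-1 at -4.03 and the lysosomal lipase gene lipl-4 at -2.1, at adjusted p = 0.31 with an estimated correlation. Both fat lists that passed the 2 tests for Rheb RNAi passed camera alone here (medians -0.68 for synthesis and -0.22 for beta-oxidation), at adjusted p = 0.18 and 0.19 with an estimated correlation. Of the cell type lists camera passed those of intestine (median -0.39, with 2 of 12 genes above 0), neuron (-0.35, 5 of 45) and germline markers (0.34, 31 of 36), at adjusted p = 0.0031, 8.2e-04 and 7.4e-05 against 0.23, 0.56 and 0.43 with an estimated correlation, and of their genes unc-18 (-0.95) alone was called, but not without any 1 of 5 arrays (control fed 2, TOR fed 1 and 3, TOR fasted 1 and 3; -0.95 to -0.87). camera passed 18 lists, 2 of which passed with an estimated correlation. By the measure described for Rheb RNAi, TOR RNAi worms kept a share of 0.760 of the control response (0.681 to 0.845), with a share of 0.424 (0.382 to 0.471) for genes that fasting raised and 0.906 (0.815 to 1.05) for genes that it lowered. The median raised gene rose by 0.6 in TOR RNAi worms and, against control worms, was at 0.93 (0.81 to 1.15) in fed and at 0.14 (-0.20 to 0.29) in fasted ones. The number of genes called was 193 without TOR fed replicate 3 and 192 without TOR fasted replicate 2. With the replicate number as a block it was 719, and 1118 when the TOR numbers, which do not pair with those of the other plates, were blocks of their own.
Set against each other, the fasting responses under TOR RNAi and Rheb RNAi differed in few genes. The response of spp-12 was less negative under TOR RNAi by 4.62 ± 0.65 (adjusted p = 0.0012), and so was that of clec-76 by 3.04 ± 0.46 and of ugt-66 by 2.78 ± 0.5. In a fit of the compared groups ugt-66 was not called. sysm-1 and dod-24 fell more with fasting under TOR RNAi, with differences of -4.01 ± 0.67 and -3.54 ± 0.39 (adjusted p = 0.0049 and 8.5e-05), as did mbug-1 (-3.29 ± 0.55) and clec-67 (-2.71 ± 0.38). limma called 39 of the 12277 genes, 23 higher and 16 lower, each changed by at least 2-fold. The anchor genes acs-2 (-0.21 ± 0.75), hsp-12.6 (0.07 ± 0.52), ins-7 (0.17 ± 0.46) and fat-7 (1.67 ± 0.71) were not called, and the SE values show the size of difference that these arrays leave open. Of the 28 lysozymes and saposins 4 had a less negative response under TOR RNAi (5 less and 1 more negative adjusted over the list alone), with spp-14 at 1.45 (not called in a fit of the compared groups) and spp-12 above, at adjusted p = 0.52 with an estimated correlation. Sperm markers (median -0.26), muscle genes (0.20) and hedgehog-related epidermal genes (0.09) passed camera, at adjusted p = 0.63, 0.67 and 0.52 with an estimated correlation. camera passed 16 lists and none passed with an estimated correlation, the lowest adjusted p being 0.14 for the genes lower with active DAF-16, of which dod-24 alone was called, against 3 adjusted over the list alone. The balance turned to 13 higher and 15 lower in a fit of the compared groups, 17 and 18 without Rheb fed replicate 3 and 13 and 17 without TOR fed replicate 2. On 1 simulated data set 9 of 81 genes called in this comparison were false (11.1%). The number of genes called was 25 without Rheb fasted replicate 2, 59 without Rheb fasted replicate 4 and 106 with the replicate number as a block.

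**Figure D4:**
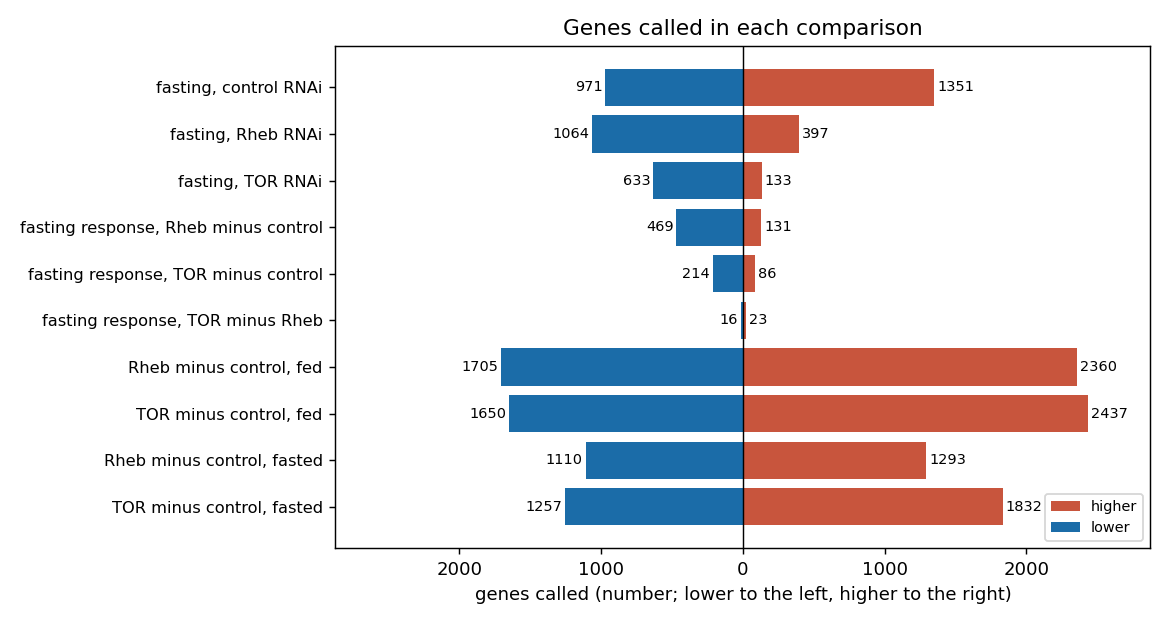
Number of the 12277 genes called by limma in each of the 10 comparisons, with bars to the right for genes that were higher and to the left for genes that were lower in the first-named group or response. RNAi in fed worms gave the most calls, 4087 for TOR RNAi and 4065 for Rheb RNAi, and the difference between the responses under TOR RNAi and Rheb RNAi the fewest, 39.

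Rheb RNAi changed more transcripts in fed worms than fasting did in control worms, and among those that rose were genes of nerve, muscle and peptide hormones. The lysozyme gene ilys-3 was higher by 6.58 ± 0.41, spp-12 by 5.39 ± 0.40, the cathepsin B-like gene cpr-2 by 4.13 ± 0.47 and ins-7 by 1.73 ± 0.29, while pud-4 was lower (-7.29 ± 0.53), as were mbug-1 (-6.56 ± 0.34), F55G11.2 (-6.40 ± 0.73) and clec-67 (-5.35 ± 0.24). Among the 12277 genes, limma called 4065, 2360 higher and 1705 lower in Rheb RNAi worms, 1477 by at least 2-fold. gst-4 was higher by 1.1 ± 0.40 (adjusted p = 0.038), a call lost without any 1 of 5 arrays (control fed 1, 2 and 3, Rheb fed 3 and 4; 0.91 to 1.01), without the 2 high-ratio arrays (0.91) and without a filter on dim probe sets (1.1). acs-2 (0.88; called at 1.22 without control fed replicate 5), hsp-12.6 (0.34), fat-7 (0.5), sod-3 (0.16), daf-16 (-0.04), nhr-49 (0.1) and vit-2 (-0.26) were not called. The fed Rheb RNAi mean of C17H12.6 was below log2 4, and its fall was at least 4.86. acs-2 (1.1) and vit-2 (-0.28) were called with the replicate number as a block, in which control and Rheb RNAi arrays pair, and vit-2 was called at -0.34 when each array was centred on its median. Other high rises were of R07C12.1 (4.75) and ugt-32 (3.62), and other falls of pud-3 (-5.82) and C17H12.6 (-5.66).

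Of 45 neuron genes 35 rose and none fell (37 adjusted over the list alone), by a median of 1.07, with the glutamate decarboxylase gene unc-25 at 1.56, the synaptic gene ric-4 at 1.47 and the neuropeptide gene flp-5 at 1.5. Of 26 muscle genes 23 rose and none fell (24 adjusted over the list alone), by a median of 1.13, with cpn-3 at 1.69, dim-1 at 1.43 and unc-89 at 1.71. unc-89 was at 0.90 averaged over its probe sets and at 1.48 without Rheb fed replicate 3. Of 21 insulin-like peptide genes 13 rose and none fell (16 adjusted over the list alone), with ins-23 at 3.17 and ins-22 at 2.51. Of 27 oocyte and eggshell genes 17 fell and 2 rose (20 and 3 adjusted over the list alone), with the chitin synthase gene chs-1 at -1.02 and the eggshell receptor gene egg-1 at -0.72, and of 36 germline genes 16 fell and 1 rose (17 and 1 adjusted over the list alone), with fbf-1 at -1.42 and pgl-1 at -0.89. With an estimated correlation the adjusted p of these 5 lists, all passing camera, were 0.31, 0.31, 0.31, 0.53 and 0.53. Zygotic embryo markers moved the other way from the oocyte and germline lists: 17 of 40 rose and 2 fell (20 and 2 adjusted over the list alone), by a median of 0.58 (adjusted p = 0.0042 with camera and 0.85 with an estimated correlation). Sperm markers had a median of -0.28 (adjusted p = 0.016 with camera and 0.93 with an estimated correlation). Of the 41 respiratory chain genes 23 rose and none fell (28 adjusted over the list alone; median 0.36), with asg-2 at 0.89 and isp-1 at 0.59 (adjusted p = 0.27 with an estimated correlation). Of the 105 cuticle collagens 44 fell and 1 rose (50 and 1 adjusted over the list alone), with col-183 at -4.49 (adjusted p = 0.53 with an estimated correlation). The 12 intestine genes went both ways, with ges-1 at -2.25 and the peptide transporter gene pept-1 at 2.11; 4 rose and 3 fell (4 and 4 adjusted over the list alone). camera passed 15 lists, none of which passed with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, passed 16. When each array was centred on its median, the calls split into 2006 higher and 2107 lower. The 3' minus middle difference of the ubiquitin control, which widens as RNA degrades, was 2.63 ± 0.72 (SD, n = 4) log2 units on the fed Rheb RNAi arrays and 1.95 ± 0.20 (SD, n = 5) on the fed control arrays, and was 3.60 on Rheb fed replicate 3.
TOR RNAi in fed worms also changed more transcripts than fasting did in control worms, and genes of nerve and peptide hormones were among those that rose. ilys-3 was higher by 6.29 ± 0.44, cpr-2 by 5.53 ± 0.52, the insulin-like peptide gene ins-23 by 4.15 ± 0.27 and lys-10 by 4.10 ± 0.61, and pud-3 (-5.89 ± 0.59), pud-4 (-5.71 ± 0.58), D1086.3 (-5.52 ± 0.38) and F54F7.2 (-5.28 ± 0.22) were lower. acs-2 was higher by 3.28 ± 0.51 (adjusted p = 5.1e-05), nhr-49 by 0.48 ± 0.17 (adjusted p = 0.030) and ins-7 by 1.72 ± 0.31, and sod-3 fell by 0.90 ± 0.20. The nhr-49 call was lost without any 1 of 5 arrays (control fed 1, 2 and 3, TOR fed 2 and 3), at 0.40 to 0.5, with arrays centred on their medians (0.36) and in a fit of the compared groups (0.48). Over the 12277 genes, limma called 4087, 2437 higher and 1650 lower in TOR RNAi worms, 1653 by at least 2-fold. hsp-12.6 (-0.05), fat-7 (-1.05; called at -1.46 without TOR fed replicate 2), gst-4 (0.54), daf-16 (-0.04) and vit-2 (0.26) were not called. gst-4 was called at 0.90 with a block by number, which does not pair TOR and control arrays. With TOR numbers 2 and 3 joined to 4 and 5 fat-7 was called at -1.39.

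Of the 45 neuron genes 33 rose and none fell (36 adjusted over the list alone), by a median of 1.27, with the neuropeptide gene flp-22 at 1.75 and ric-4 at 1.72. Of the 21 insulin-like peptide genes 17 rose and none fell in both adjustments, with ins-22 at 3.33 and ins-17 at 1.66. Of the 26 muscle genes 7 rose and none fell in both adjustments, by a median of 0.42, with cpn-3 at 1.07 and the titin gene ttn-1 at 1.06. The other 5 probe sets of ttn-1 were at -0.68 to 0.53, and averaged over all 6 it was at 0.03 and not called. Of the 27 oocyte and eggshell genes 20 fell and 1 rose (21 and 1 adjusted over the list alone), with the yolk receptor gene rme-2 at -1.31. Of the 105 cuticle collagens 64 fell and 2 rose (77 and 3 adjusted over the list alone), with col-101 at -4.21 and col-19 at -3.27. With an estimated correlation the adjusted p of these 5 lists, all passing camera, were 0.36, 0.36, 0.94, 0.38 and 0.38. Of the 40 zygotic embryo markers 11 rose and 2 fell (12 and 2 adjusted over the list alone), by a median of 0.55 (adjusted p = 0.036 with camera and 0.98 with an estimated correlation). Germline markers (12 of 36 fell and 2 rose in both adjustments) and hedgehog-related epidermal genes (8 of 34 fell and 4 rose in both adjustments) had medians of -0.38 and -0.21 and passed camera, at adjusted p = 0.89 and 0.89 with an estimated correlation. Of 26 genes of the TOR pathway 4 fell and 2 rose (3 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.48 with camera). The falls were of let-363, of the TORC2 genes rict-1 (-1.22) and sinh-1 (-0.89) and of akt-2 (-0.62), and the rises of pha-4 (0.84) and sgk-1 (0.74). The call of akt-2 was lost without any 1 of 15 of the 24 arrays, namely all but control fed 2 and 5, control fasted 2 and 3, Rheb fed 1, 2 and 3, Rheb fasted 3 and TOR fed 3 (-0.63 to -0.45; -0.95 and called without the last). It was also lost, at -0.62, in a fit of the compared groups, without a filter on dim probe sets and without the _s_at and _x_at types. The call of sgk-1 was lost without any 1 of the 3 TOR fed arrays (0.73 to 0.75). Added bacterial control RNAs differed too on the fed TOR RNAi arrays, bioB by -0.6 to -0.24 over its probe sets, bioC by -0.40 to -0.3, bioD by -0.20 to 0.05 and the brighter cre by 0.07 to 0.13. The change of nhr-49 lies within such sizes. sinh-1 had a mean below log2 4 in fed TOR RNAi worms, and was at -0.75 with array values below 4 set to 4 and at -0.56, still called, averaged over its probe sets. pha-4 was at 0.45 and not called without the _s_at and _x_at probe sets, where its other probe set reads it. camera passed 14 lists, none of which passed with an estimated correlation, and fry passed 12. A block by number gave 6655 calls. Without TOR fed replicate 3 the number of genes called was 2570, and ttn-1 (0.83) and sinh-1 (-0.69) were not called. When each array was centred on its median, which moved the median change of all genes from 0.0366 to -0.09, the calls split into 1882 higher and 2280 lower.

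**Figure D5:**
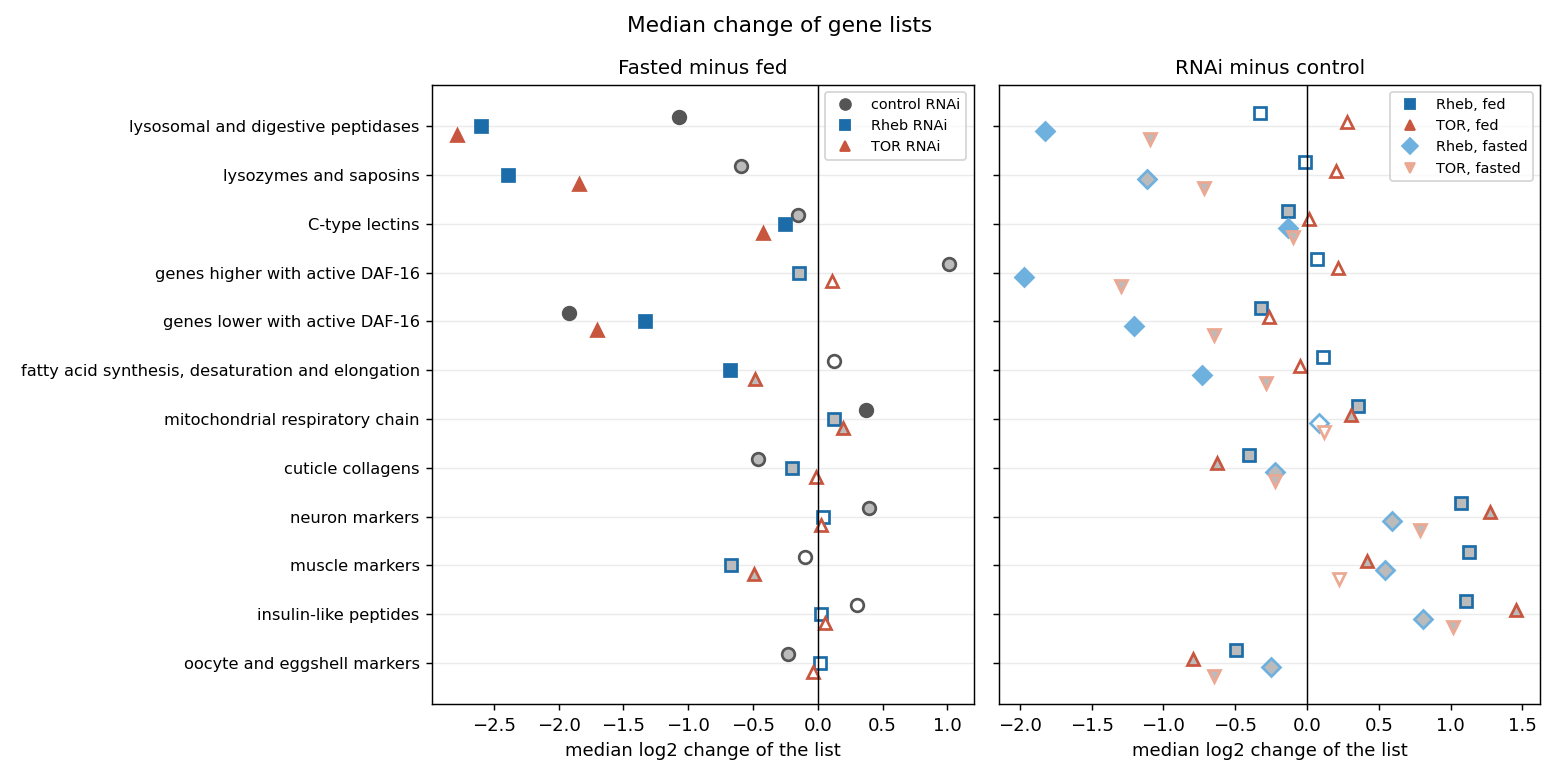
Median log2 change (x axis) of 12 gene lists under fasting on each kind of plate (left) and under each knockdown in fed and in fasted worms (right), with filled points where limma's camera passed with both the preset and the estimated correlation, grey points where only the preset correlation passed and open points where neither did. The peptidase median was -1.07 with fasting in control worms, -2.6 in Rheb RNAi worms and -2.78 in TOR RNAi worms.

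In fasted worms Rheb RNAi lowered transcripts of digestion, fat desaturation and the DAF-16 list. mbug-1 was lower (-7.51 ± 0.34), as were asp-17 (-6.30 ± 0.29), asp-13 (-6.08 ± 0.45), lys-2 (-6.13 ± 0.41) and lys-7 (-5.57 ± 0.3), whereas ins-7 was higher by 4.72 ± 0.29 and nep-14, a neprilysin-like peptidase gene, by 2.87 ± 0.3. acs-2 fell by 3.0 ± 0.47 (adjusted p = 5.2e-05), hsp-12.6 fell by 1.88 ± 0.32 (adjusted p = 1.7e-04), fat-7 fell by 2.62 ± 0.44 and sod-3 fell by 0.75 ± 0.18. In all, of 12277 genes, limma called 2403, 1293 higher and 1110 lower in Rheb RNAi worms, 1000 by at least 2-fold. gst-4 (-0.25), daf-16 (-0.04), nhr-49 (0.17) and vit-2 (-0.31) were not called. Where means were below log2 4, the falls of asp-17, asp-13 and fat-7 were at least 5.73, 5.20 and 2.44 and the rise of nep-14 at least 1.76. vit-2 was called at -0.33 with the replicate number as a block and at an unchanged -0.31 with an intensity trend in the variance model. Of the 18 genes higher with active DAF-16 12 fell and none rose (13 and 2 adjusted over the list alone), with dod-3 at -4.37 and cyp-34A9 at -4.28, and of the 11 genes lower with active DAF-16 7 fell too (8 adjusted over the list alone), ins-7 being the 1 that rose. Of the 22 peptidases 14 fell and 2 rose (14 and 3 adjusted over the list alone), of the 99 C-type lectins 36 fell and 6 rose (38 and 6 adjusted over the list alone), with clec-50 at -4.65, and of the 17 genes of fatty acid synthesis, desaturation and elongation 11 fell and 1 rose in both adjustments, with elo-5 at -3.77 and fat-6 at -1.98. These 5 lists were the ones that passed both camera and an estimated correlation, the highest adjusted p being 0.031 (fatty acid synthesis). Of the 45 neuron genes 13 rose and none fell (21 adjusted over the list alone), with unc-25 at 1.08 (adjusted p = 0.34 with an estimated correlation). Zygotic embryo markers, of which 14 of 40 rose and 1 fell (16 and 1 adjusted over the list alone), muscle genes, of which 7 of 26 rose (9 adjusted over the list alone), and the oocyte and eggshell and intestine markers, with medians of -0.25 and -0.28, also passed camera, at adjusted p = 0.47, 0.40, 0.56 and 0.23 with an estimated correlation. The lipase gene lipl-5 was at -5.11 and lipl-4 at -4.23. The balance of higher and lower genes turned to 951 and 959 in a fit of the compared groups, 1021 and 1024 without control fasted replicate 1 and 826 and 920 without Rheb fasted replicate 3. A block by replicate number gave 4289 called genes.
TOR RNAi in fasted worms raised ins-7 by 4.87 ± 0.31, F10C2.7 by 4.64 ± 0.49 and the amiloride-sensitive channel gene acd-1 by 3.36 ± 0.20. The last 2 had fasted control means below log2 4, and their rises were at least 3.50 and 3.14. mbug-1 (-5.59 ± 0.37), F54F7.2 (-5.08 ± 0.22), dod-24 (-4.8 ± 0.27) and lys-2 (-4.71 ± 0.45) were lower. hsp-12.6 fell by 2.2 ± 0.35, fat-7 fell by 2.51 ± 0.48 and sod-3 fell by 1.21 ± 0.20, while acs-2, higher in fed TOR RNAi worms, was not called in fasted ones (-0.81 ± 0.51, adjusted p = 0.25). Among the 12277 genes, limma called 3089, 1832 higher and 1257 lower in TOR RNAi worms, 1202 by at least 2-fold. gst-4 (0.11), daf-16 (-0.29), nhr-49 (0.29) and vit-2 (-0.01) were not called. daf-16 (-0.53) and nhr-49 (0.41) were called with the replicate number as a block. Of the 45 neuron genes 27 rose and none fell (29 adjusted over the list alone), with flp-8 at 2.1, of the 21 insulin-like peptide genes 13 rose and none fell (17 adjusted over the list alone), with ins-23 at 2.69, and of the 27 oocyte and eggshell genes 19 fell and none rose (21 and 1 adjusted over the list alone), with cpg-1 at -1.11. Of the 18 genes higher with active DAF-16 12 fell and 2 rose in both adjustments, with dod-3 at -3.20, and of the 22 peptidases 13 fell and 3 rose in both adjustments, with asp-17 at -4.49 against a rise of cpr-4 (1.72). With an estimated correlation the adjusted p of these 5 lists, all passing camera, were 0.32, 0.3, 0.31, 0.3 and 0.3. camera passed 16 lists, none of which passed with an estimated correlation, and fry passed 20. A block by number gave 5951 calls, and omitting TOR fasted replicate 2 gave 1733. On that array the 3' minus middle difference of the ubiquitin control was 2.79, against 1.74 and 1.95 on TOR fasted replicates 1 and 3, without which 2689 and 2085 genes were called.

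Across the 12277 genes, the log2 effects of Rheb RNAi and TOR RNAi against control correlated at Pearson's r = 0.795 in fed and 0.784 in fasted worms. Genes are not independent replicates, and both effects share the control arrays, which alone gave r = 0.408 and 0.410 in 100 simulations of unchanged groups. The covariance was 0.429 in fed and 0.356 in fasted worms, against simulated values of 0.0239 and 0.0241. With the control arrays split between the comparisons, r averaged 0.723 (0.566 to 0.793 over 20 splits) in fed and 0.696 (0.525 to 0.814) in fasted worms. In fed worms, 1636 genes were called higher and 960 lower under both knockdowns, against 468 and 229 for independent lists of these sizes. With the control arrays split, which also leaves fewer in each comparison, they averaged 962 (811 to 1084) and 531 (397 to 618), and independent lists 244 and 114. ilys-3, cpr-2, ins-22 and ins-23 were among those higher, and pud-3, pud-4, col-183 and clec-67 among those lower under both.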

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

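The fed starting level of the raised genes, the level that all fasting changes kept, the comparisons of the neuron and muscle lists with other somatic genes and the replicate numbers over array control probe sets were tests chosen only after the results were seen, and the other explanations were tested by predictions written down before.

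The fasting response differed between plates in many genes, tested as an interaction. Between Rheb RNAi and control RNAi 600 genes differed, and of those named in the report the log2 differences were acs-2 -3.88, asg-2 -0.77, asp-17 -5.18, C05D12.3 4.52, C17H12.6 5.40, clec-67 4.74, cpr-2 -6.14, csr-1 1.23, cyp-34A9 -5.31, dod-3 -3.34, ech-7 -3.66, elo-6 -3.16, fat-5 -3.11, fat-6 -1.73, fat-7 -3.13, ges-1 -1.43, hacd-1 -4.07, hsp-12.6 -2.22, ilys-3 -6.22, ins-7 2.98, lys-7 -5.51, lys-8 -2.26, nduf-5 -0.72, pck-2 -1.14, sod-3 -0.91, spp-12 -5.11, ssp-10 -0.86 and tps-1 -1.3. Between TOR RNAi and control RNAi 300 genes differed, among them acs-2 -4.09, asp-17 -4.83, asp-3 -2.91, C17H12.6 4.08, col-101 2.28, col-158 1.45, col-183 3.68, cpr-1 -3.62, cpr-2 -6.99, dod-3 -2.42, F46F2.3 4.44, hsp-12.6 -2.15, ilys-3 -5.0, ins-7 3.16, lipl-1 -4.03, lipl-4 -2.1, lys-10 -4.68, lys-7 -3.24 and unc-18 -0.95. Between TOR RNAi and Rheb RNAi 39 genes differed, among them clec-67 -2.71, clec-76 3.04, dod-24 -3.54, mbug-1 -3.29, spp-12 4.62, spp-14 1.45, sysm-1 -4.01 and ugt-66 2.78.

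Genes that fasting raised in control worms rose less under both knockdowns, and 3 explanations were tested. If the knockdown arrays had compressed every change, lowered genes would have lost as much, but over the 10 choices of control arrays they kept at least 0.851 of the control response under Rheb RNAi and 0.815 under TOR RNAi, against at most 0.471 for raised genes. A ceiling of the intensity scale would have spared dim genes, yet raised genes dimmer than their median kept 0.304 and 0.432, against 0.271 and 0.417 for brighter ones. The median raised gene started nearer the fasted level, by 0.89 and 0.93. Fed shift over lost rise (1.03 and 1.22) is no separate test, as lost rise is fed minus fasted shift. Other values speak against this start as the whole account. Lowered genes also started toward the fasted level, by medians of -0.94 and -0.7, but of a median control response of -1.84 they lost -0.19 (-0.36 to 0.08 over the choices) and -0.36 (-0.58 to -0.03), so that this counts for less under TOR RNAi. hsp-12.6 was at 0.34 and -0.05 in fed knockdown worms but lost 2.22 and 2.15 of its rise, and acs-2 was at 0.88 under Rheb RNAi but lost 3.88. Under TOR RNAi acs-2 goes with it, being higher by 3.28 in fed worms against a lost rise of 4.09. A higher fed level may thus account for the lost rise of the median raised gene, but not of hsp-12.6 or, under Rheb RNAi, acs-2. Whether less feeding or a change inside the worm raised that level stays open.

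Of 45 neuron genes 35 (Rheb RNAi) and 33 (TOR RNAi) were higher in fed knockdown worms, and the medians were 1.07 and 1.27, but as a list they passed camera only with its preset correlation and not with an estimated one (adjusted p = 0.31 and 0.36). None of the 45 genes is held by another list, and the brightest of them, snb-1, egl-3 and egl-21, were at log2 intensities of 12.17, 9.07 and 9.29 in fed control, 12.46, 10.38 and 10.10 in fed Rheb RNAi and 12.44, 10.45 and 10.51 in fed TOR RNAi worms. A smaller share of germ cells and eggs would have raised all somatic transcripts alike, but these moved apart. The median of 151 intestine, hedgehog-related and cuticle collagen (105) genes was -0.3 and -0.46. It lay below the neuron median by 1.37 (95% bootstrap over genes, not arrays, 1.07 to 1.66) and 1.73 (1.35 to 2.04). Each of the 3 lists alone was lower too, the intestine markers by 1.3 (0.564 to 2.0) and 1.22 (0.447 to 1.72). Muscle lay above these 151 genes by 1.42 (1.25 to 1.6) and 0.877 (0.716 to 1.15). It was not among them, being grouped with neurons before the pattern was narrowed. The neuron median differed from the muscle median by -0.0552 (-0.378 to 0.284) under Rheb RNAi, where both rose alike, and by 0.851 (0.434 to 1.16) under TOR RNAi. As the 151 genes may have moved for other reasons, such a share stays open for the rise of neuron and muscle transcripts. Fewer germ cells and eggs go with the oocyte and eggshell list, in which 17 and 20 of 27 genes fell (medians -0.5 and -0.8), and the germline list, in which 16 and 12 of 36 fell (-0.42 and -0.38). Fewer eggs would also lower zygotic embryo markers, of which 17 and 11 of 40 rose and 2 and 2 fell (0.58 and 0.55). With an estimated correlation none of the 3 lists passed, at adjusted p = 0.53 and 0.38 (oocyte and eggshell), 0.53 and 0.89 (germline) and 0.85 and 0.98 (embryo). Scaling of middling intensities did not reach it, since 2.5% of the medians of 10000 random lists of matched brightness lay above 0.213 and 0.263. Degraded RNA on Rheb fed replicate 3 alone did not carry it, the median being 1.09 without that array. Rheb fed 1 and 4 also exceeded all fed controls in 3' to middle ratio. Group-wide degradation, a change within nerve cells and a larger share of nerve may remain, untested.

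The replicate numbers of control and Rheb RNAi arrays paired, with correlations of deviations from group means of 0.451 to 0.663 between fed control and fed Rheb RNAi arrays and 0.227 to 0.517 between the fasted ones, but those of TOR RNAi arrays did not pair with them (-0.348 to 0.253). TOR replicates 2 and 3 may come from the experiments numbered 4 and 5, which was noticed over genes, where the 3 assignments with these numbers ranked 1 to 3 of 60. Over 1029 probe sets naming no single gene, these assignments had mean correlations of at least 0.213, against at most 0.153 for the other 57 of the 60. Over genes, the numbers as given reached 0.0248 and ranked 26 of 60. Over 77 array control probe sets the same assignments ranked only 11 to 40, with mean correlations of -0.0535 to 0.136 against 0.238 for the highest other, which does not support the renumbering. The probe sets share the genes' arrays, the labels do not settle this, and no sample was renumbered in the counts of the report.

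Single arrays lay far from their group in 20 of 345 gene and group pairs (5.8%, by chance about 1 in 20). TOR RNAi groups (3 arrays) were not tested. Values are log2 intensities. In fed control worms these were cpr-4 13.09 (lowest, replicate 4, next 13.57), F55G11.2 13.57 (highest, replicate 4, next 10.95), far-7 7.72 (highest, replicate 5, next 6.49), fbf-1 9.43 (highest, replicate 4, next 8.85), hsp-12.3 8.0 (highest, replicate 5, next 6.37), lipl-5 12.29 (highest, replicate 5, next 11.32), sinh-1 5.64 (highest, replicate 4, next 4.74) and sod-3 6.41 (highest, replicate 1, next 6.23). In fasted control worms these were acd-1 4.07 (highest, replicate 4, next 3.74), F10C2.7 4.20 (highest, replicate 5, next 2.81), icl-1 12.94 (lowest, replicate 2, next 13.41), lys-2 12.04 (highest, replicate 3, next 10.97) and sysm-1 8.62 (highest, replicate 3, next 7.42). In fed Rheb RNAi worms these were clec-41 8.18 (lowest, replicate 4, next 8.72), fat-3 13.24 (highest, replicate 3, next 12.85), lbp-7 8.17 (highest, replicate 4, next 7.31), pck-2 12.07 (highest, replicate 4, next 11.94), pgl-1 10.25 (highest, replicate 2, next 9.72) and unc-89 10.02 (highest, replicate 3, next 9.13). In fasted Rheb RNAi worms these were fat-7 4.53 (highest, replicate 4, next 3.79).

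Probe sets that name no single gene were outside the comparisons of the report. Of 1029 of them, limma called 138 for fasting in control worms, 79 in Rheb RNAi worms and 36 in TOR RNAi worms, 258 and 295 for Rheb RNAi and TOR RNAi in fed worms, and 117 and 156 in fasted worms. Between the fasting responses it called 38 for Rheb RNAi against control RNAi, 8 for TOR RNAi against control RNAi and 4 for TOR RNAi against Rheb RNAi.

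Over other splits of the same arrays, ignoring pairs of numbers, chance could be excluded for fasting in control worms (2322 genes, highest other 664). So it could for Rheb RNAi in fed worms (4065, 2922) and TOR RNAi in fed (4087, 2208) and fasted worms (3089, 2336). The splits cannot tell for differing responses of Rheb RNAi and control (600, 46), TOR RNAi and control (300, 2) and TOR and Rheb RNAi (39, 1). There, mixing plates adds the RNAi effect to the spread and can lower the calls. Rheb RNAi in fasted worms called 2403 genes and another split 2412, and its response differed from that of control RNAi in 22 lists, where another split gave 24. As large were 2 and 4 of all 100 splits, and 2 and 1 of the 11 that part all 4 pairs of numbers as the real one does, too few for a share under 0.05. The split with 2412 genes set control replicates 1 to 4 against Rheb RNAi with control replicate 5, so that it differs from the real one in the side of that array alone, and with the number as a block 4289 genes were called. Chance could not be excluded for the lists moved by fasting in control worms (22, 26; 5 of 100 splits as large), for the lists with a different response under TOR RNAi (18, 24; 9 of 56) or for fasting under Rheb RNAi (1461, 1626; 2 of 35). There the larger split exchanged 1 fed with 1 fasted array, and splits parting all 4 pairs gave at most 0. Splits parting as many pairs as the real one, 11 or 12 and so also too few, gave at most 0 genes and 26 lists for fasting in control worms, 24 genes and 21 lists for the response under Rheb RNAi and 2922 genes for Rheb RNAi in fed worms. For fasting under TOR RNAi the splits are too few (766, highest other 3).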

How the results depend on the processing

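The blocks that treat the TOR numbers apart or renumber them, and the fit without the 2 arrays of highest 3' to middle ratio, were tests chosen only after the result was seen, and the other alternatives were fixed before the data were examined. No named gene changed sign while called, but the balance of some counts did turn, as given with the report for Rheb RNAi and TOR RNAi in fed worms, Rheb RNAi in fasted worms, TOR RNAi against Rheb RNAi and fasting under Rheb RNAi. The last, with 397 higher and 1064 lower, also gave 2176 and 1646 with the TOR numbers as blocks of their own. Lists moved by fasting in control worms (9 up and 13 down) were 15 and 14 without a filter on dim probe sets and 13 and 11 with fry.

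With the replicate number as a fixed block, as a random effect, and with the TOR numbers as blocks of their own, counts of called genes were 3883, 3798 and 4697 for fasting in control worms, 2960, 2802 and 3822 for fasting under Rheb RNAi, 1298, 1257 and 1769 for fasting under TOR RNAi, 1417, 1374 and 2148 for the response under Rheb RNAi against control, 719, 691 and 1118 for that under TOR RNAi against control, 106, 116 and 157 for TOR RNAi against Rheb RNAi, and 4289, 4040 and 5065 for Rheb RNAi in fasted worms. Why blocks raised the counts was not tested. TOR RNAi gave 6655 and 6379 genes in fed and 5951 and 5571 in fasted worms with the first 2 kinds of block. The numbers in these blocks do not pair TOR and control arrays. Rheb RNAi in fed worms gave 6487 genes with the third. With TOR numbers 2 and 3 joined to 4 and 5, the counts were 1689 for fasting under TOR RNAi, 1092 for the response under TOR RNAi against control and 146 for that against Rheb RNAi.

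The cause was not tested for the following. The count for TOR RNAi against Rheb RNAi was 82 with array weights and, with fewer probe sets tested, 24 without the _s_at and _x_at types, which also took the share kept under Rheb RNAi to 0.682. Without the 2 arrays of highest 3' to middle ratio, 185 genes differed in response between TOR RNAi and control RNAi and TOR RNAi called 1748 in fasted worms. rheb-1 was called at -0.63 (array weights) and -0.48 (TOR numbers as blocks of their own) in fasted worms, and, averaged over its probe sets, at -1.43 in fed and -1.18 in fasted worms, which mixes in the lower probe set. With an estimated correlation 3, 4 and 2 lists passed for fasting in control worms and for the responses under Rheb RNAi and TOR RNAi, and fry passed 14 and 9 of the last 2.

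Calls of named genes that an alternative ended are given with the report and the other observations. As a random effect the replicate number gave calls of gst-4 (-1.35) in the response under Rheb RNAi, of gst-4 (0.78) and nhr-49 (0.37) under TOR RNAi in fed and fasted worms and of vit-2 (-0.27 and -0.32) under Rheb RNAi in fed and fasted worms. With the TOR numbers as blocks of their own these were gst-4 (-1.35) and vit-2 (-0.28 and -0.33) in the same comparisons with Rheb RNAi and acs-2 (1.1) under Rheb RNAi in fed worms, and with TOR numbers 2 and 3 joined to 4 and 5 gst-4 (-0.93) for fasting under TOR RNAi. vit-2 in fasted Rheb RNAi worms was also called at -0.31 with an intensity trend and a robust prior.

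Leaving out 1 array at a time gave 192 to 306 genes for the response under TOR RNAi against control, 25 to 59 for TOR RNAi against Rheb RNAi, 2570 to 4350 for TOR RNAi in fed worms and 1733 to 3561 for TOR RNAi in fasted worms. The other counts stayed within 1.5 times their value. let-363 passed in all 37 alternatives in both states, at -1.69 to -1.35. On simulated data, changes of 2-fold were recovered in 79.7% of cases for fasting in control worms and in 30.8% for the response under TOR RNAi against control, 41.9% for that under Rheb RNAi against control and 23.7% for TOR RNAi against Rheb RNAi. Of the genes called there, 3 of 139 (2.16%), 0 of 75, 7 of 93 (7.53%) and 9 of 81 (11.1%) were false. They were 6 of 120 (5.0%) for fasting under TOR RNAi and 8 of 139 (5.76%) for TOR RNAi in fed worms, so that 3 of the 6 comparisons simulated lay above the 5% aimed at.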

Other observations

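No test of this part was chosen after its result was seen, since it gives values without a test beyond those of limma described with the report.

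Genes named by the fixed rule had further values in fed worms that the report does not describe. Under Rheb RNAi 2 of 26 TOR pathway genes fell, the TORC2 gene rict-1 (-1.06 ± 0.17) and sesn-1 (-0.68 ± 0.23), and 2 rose, hlh-30 (0.92 ± 0.35) and pha-4 (0.61 ± 0.19), against 1 and 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.49 with camera). The call of sesn-1 was lost without any 1 of 4 arrays (control fed 3 and 4, Rheb fed 1 and 2; -0.63 to -0.58), that of pha-4 without control fed 4 or Rheb fed 2 (0.49 or 0.46), and that of hlh-30 without any 1 of 11 arrays (control fed 3, 4 and 5, control fasted 2 and 3, Rheb fed 1, 2 and 3, Rheb fasted 3, TOR fed 3 and TOR fasted 3; 0.70 to 0.95). Calls were also lost under other alternatives: that of pha-4 without the _s_at and _x_at probe sets (0.32), with a further quantile normalization (0.45), averaged over its probe sets (0.47) and in a fit of the compared groups (0.61), and that of hlh-30 averaged over its probe sets (0.66), with arrays centred on their medians (0.84), without the 2 arrays of highest 3' to middle ratio (0.95), and, at 0.92, without a filter on dim probe sets and in a fit of the compared groups. rict-1 was at -1.84 and called without the _s_at and _x_at probe sets. The lysosomal lipase gene lipl-5 was at -2.53 ± 0.3 and the aspartyl protease gene asp-8 at -2.65 ± 0.31.

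Called genes that had another probe set called as well numbered 2 to 536 by comparison, and in at most 3 of them (of 536, for TOR RNAi in fed worms) the 2 went opposite ways. Genes such as rheb-1, with 1 probe set called and another not, are outside this count.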
